A study of Mus musculus with 9 samples.

How the data were processed

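The series holds RNA sequencing of primary mouse pro-B cell cultures, 9 libraries in 3 groups of 3. Per the labels' protocols, bone marrow of mice aged 6 to 8 weeks was plated after red cell lysis in methylcellulose medium with interleukin-7, and the colonies of a culture were pooled after 7 days. RNA was taken from the same number of cells per sample, and 1 µl of the ERCC spike-in mix, diluted 1 in 1000, was added to each RNA sample so that values could be scaled per cell. ERCC spike-ins are synthetic RNAs of known concentration that belong to no mouse gene. Polyadenylated RNA was then sequenced from a TruSeq library. The labels number the samples of each group as biological replicates. Which animals they came from is not given in the sources used here, so p-values measure the spread between these samples.

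The groups are wild-type littermates, mice that overexpress Hmgn1, and Ts1Rhr mice, which carry an extra copy of the segment of mouse chromosome 16 from Cbr1 to Fam3b. The labels give a C57BL/6 background for the Hmgn1 mice and an FVB by C57BL/6 F1 background for Ts1Rhr. The mutant groups thus differ in background by the labels, so genotype and strain cannot be told apart between them. The background of the wild-type littermates is not given in the sources used here. A single background could not match both mutant groups, so strain may differ in the comparisons with wild type too. Hmgn1 encodes a nucleosome-binding protein and lies inside the triplicated segment.

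The authors deposited 2 tables, both of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), with 1 column per library. HISAT, Cufflinks 2.0.0 and the mouse build mm9 are named per the submitters' processing notes. Their settings and the gene annotation are not given in the sources used here. The raw table holds FPKM before spike-in scaling. The library medians of its expressed genes were nearly equal, between 3.66 and 3.69 on the log2 scale, so some scaling between libraries was already in the deposited FPKM. The second deposited FPKM table was normalised further by the authors. The labels state that the spike-ins were added for normalisation per cell, and the library medians of the spike-in rows lie closer together in it. It is therefore called spike-in normalised here, though how it was made is not given in the sources used here. From its values, each library's normalised FPKM is a smooth function of the raw FPKM plus about 0.1, and the correction differs with expression level and library. None of its values was 0, and the 7187 rows at 0 in all 9 raw columns lay between 0.0891 and 0.110. Over the 26 spike-in rows with a mean of at least 1 FPKM, the mean absolute deviation of the library medians fell from 0.171 in the raw table to 0.0434 in the normalised one, on the log2 scale. The mean SD within these rows fell only from 0.588 to 0.509, so single spike-ins still varied between libraries.

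FPKM are not counts, so no count test was run and the sequencing depth is unknown. Steps between low raw values gave only a rough relative depth of 0.753 to 1.62 against wild-type replicate 3, resting on a step shared by 15 to 66 of 191 to 444 low genes per library. The raw table lists 24 tested rows at exactly 0.01 in some library, among them Rpl26, a ribosomal protein gene that cells need. Such an entry can be a failed estimate, so these rows are described only as listed at that value.

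Of 23398 rows, 92 were spike-ins and 27 carried calendar dates in place of symbols, of which 16 had a mean of at least 1 FPKM. Both kinds were left out of the tests. Among the other 23279 rows, the 10878 with a mean raw FPKM of at least 1 over the 9 libraries were tested, in both tables. Raw values entered as log2(FPKM + 0.1). The normalised values entered as their log2, since about 0.1 was already inside them. Folds on this scale understate the change of low genes. The test was limma 3.58.1 in R 4.3.3, with an intensity trend, all 9 libraries in 1 fit with a mean per group, two-sided p, Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Replicate numbers were not used as a block, for nothing in the labels ties equal numbers to a litter, batch or day.

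The global level was each library's median log2 FPKM over the tested genes, compared between groups by an exact two-sided permutation test, which cannot go below 0.1 for 3 libraries against 3. The triplicated region was compared with all other genes by the difference of median log2 fold changes, with 100000 random lists matched on mean expression. Such a p treats genes as units. Gene neighbourhood came from the RefSeq annotation of the GRCm38.p6 assembly, which is not the build of the files, so it served only for gene order and no coordinates are given. Symbols matched for 10824 of the 10878 tested genes. Fold changes of the mutant groups share the wild-type libraries, so their correlation was set beside 100 simulated draws of unchanged groups against the same controls.

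A set of 30 gene lists was fixed from textbook knowledge before the data were examined, as were the tests, the groups and most of the alternative settings. Lists with at least 5 tested members, 23 in all, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists of a comparison. The rule for named genes was also fixed then. It took Hmgn1, up to 6 genes of the triplicated region, the 8 largest increases and 8 largest decreases among called genes with no overlap between groups and a mean of at least 5 FPKM (leaving out small RNAs, immunoglobulin segments, joined symbols and symbols of predicted or unnamed genes), and up to 3 members of each list by smallest p, from which the text takes a part, and 1 gene that the rule names is not reported here. Genes named outside that rule are marked as chosen after their values were seen.

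The steps were tested on simulated data for Ts1Rhr against wild type, with the means and residual spread of the 10878 genes and 50 genes changed at each of 4 fold sizes. On simulated normalised values, 0 of 50 genes changed 1.5-fold were called, 9 of 50 at 2-fold, 32 of 50 at 3-fold and 39 of 50 at 4-fold, with 2 false calls. On simulated raw values these were 6, 29, 41 and 46 of 50, with 7 false calls. Without any change, 0 genes were called in either. The noise was drawn independently for each gene and library, so shifts that genes of a library share were left out. False calls from such shifts are not measured by these figures.

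Alternatives covered the pseudocount, the filter on low values, the groups in the fit, a replicate block, library weights, each library left out in turn, and other scalings, among them 1 spike-in factor per library from the summed spike-in FPKM. Correlations between libraries were 0.892 to 0.953 over the tested genes, so no library looked deposited more than once. Nothing in the labels gives a sequencing batch.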

Results

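The data set covered 9 RNA libraries from primary mouse pro-B cell cultures, with 3 wild-type, 3 HMGN1-overexpressing and 3 Ts1Rhr libraries. Per library, 12951 to 14252 genes were above 0 in the raw FPKM table and 10720 to 10893 reached 1 FPKM. Spike-in rows made up 0.2% to 0.343% of the summed raw FPKM, and 38 to 43 of the 92 were above 0. The series title poses the question of whether an extra copy of the region raises transcription as a whole through HMGN1. Values below are spike-in normalised FPKM unless raw FPKM are named, as mean ± SD with n = 3, and folds are on the log2 scale with the 0.1 that the values hold.

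Transcripts of myeloid cells were abundant in these cultures. The highest mean raw FPKM of the tested genes belonged to Lyz2, the lysozyme of macrophages and granulocytes, with 2.67% to 5.19% of the summed raw FPKM per library. Its share was 4.45% ± 0.645 in wild type, 3.69% ± 1.19 with HMGN1 overexpression and 3.15% ± 0.268 in Ts1Rhr. Wild-type replicate 1 stood apart, with 23.1% of its raw sum in its top 10 genes and 10510 FPKM of the ribosomal RNA row Rn45s. Ts1Rhr replicate 3 alone carried Y-linked transcripts at a high level, with Ddx3y at 41.8 and Eif2s3y at 73.6 raw FPKM, and its Xist level was 0.443 FPKM. In all other libraries Xist lay between 94.2 and 193 raw FPKM. By these levels Ts1Rhr replicate 3 is male and the other libraries are female. Sex is therefore not balanced between Ts1Rhr and the other groups, and its effect was not tested.

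Hmgn1 lies in the triplicated segment. In Ts1Rhr its level was 121 ± 6.01 FPKM against 64.4 ± 15.2 in wild type, a fold of 1.92 (limma, adjusted p = 0.0909). On raw FPKM, where libraries varied less, the values were 126 ± 0.693 and 62.0 ± 4.66, with an adjusted p of 0.00923. In the HMGN1-overexpressing group the row stood at 84.6 ± 14.3 FPKM, a fold of 1.33 over wild type that did not pass (limma, adjusted p = 0.54). Its raw level there was 74.2 ± 2.73 FPKM (limma, adjusted p = 0.345). The species of the transgene is not given in the labels, and a transgene from another species would not be fully counted in this row.

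The global level of neither mutant group differed from wild type by more than the spread between libraries. The mean library median was 3.71 ± 0.19 (log2, n = 3) in Ts1Rhr and 3.58 ± 0.17 in wild type, a difference of 0.13 with a standard error of 0.15 and a fold of 1.10 (exact permutation p = 0.5, two-sided). With HMGN1 overexpression it was 3.79 ± 0.30, which is 0.21 above wild type with a standard error of 0.20 and a fold of 1.15 (exact permutation p = 0.4). The smallest p that this design can give is 0.1. Across genes, 59.9% were higher in Ts1Rhr than in wild type and 72.7% with HMGN1 overexpression. The median gene lay 0.12 and 0.21 above wild type, against 0.01 in both on raw FPKM. Raw library medians were nearly equal in all groups, so raw FPKM cannot show a global shift either way.

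The sign of the global difference in Ts1Rhr depended on how the spike-ins were used and on how a library was summarised. With 1 spike-in factor per library in place of the authors' curve, the Ts1Rhr difference was -0.07 (exact permutation p = 0.7). For the log2 of the summed FPKM, on the same deposited normalised values, it was -0.36 (exact permutation p = 0.4). That sum was 827155 in WT replicate 1 against 553985 and 392907 in WT replicates 2 and 3, and abundant genes weigh most in it. The HMGN1 difference was 0.19 with 1 factor (exact permutation p = 0.5) and -0.01 for the summed FPKM (exact permutation p = 1). Leaving out HMGN1_OE replicate 2 lowered it to 0.06, and leaving out HMGN1_OE replicate 1 raised it to 0.35. The Ts1Rhr difference was 0.04 without Ts1Rhr replicate 1 and also without WT replicate 3, 0.22 without Ts1Rhr replicate 3 and 0.21 without WT replicate 1. Between the mutants, Ts1Rhr lay at -0.07 relative to HMGN1 overexpression with a standard error of 0.20 (exact permutation p = 0.8). With 1 spike-in factor, a comparison chosen after seeing the data, it lay at -0.26 (exact permutation p = 0.1, the smallest possible) with 1877 of 10878 genes higher, against 4082 on the deposited values.

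**Figure D1:**
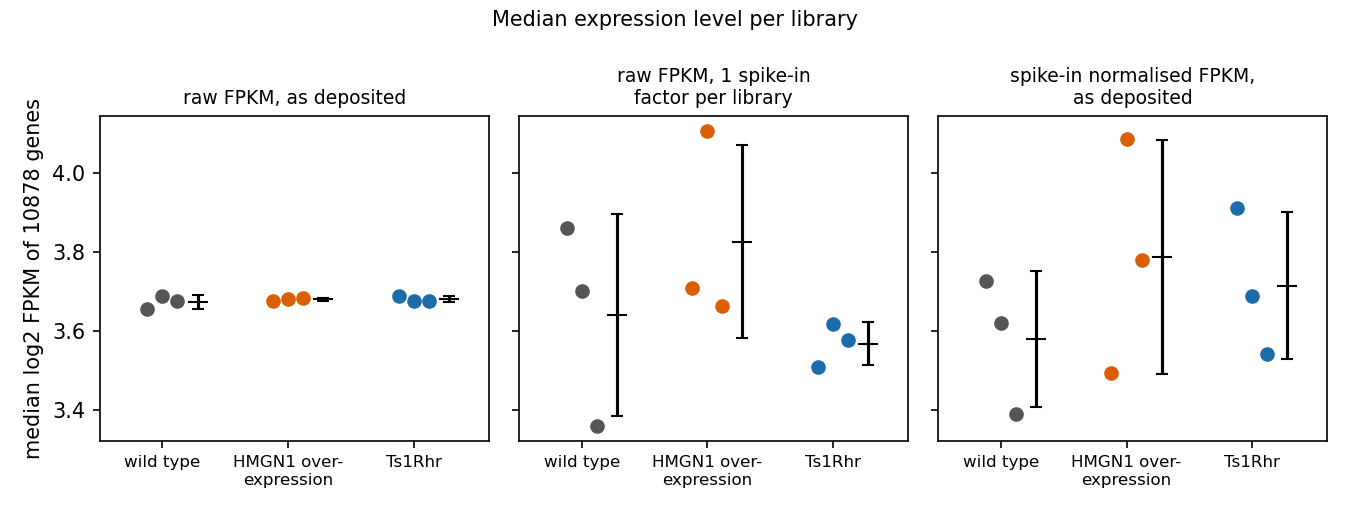
Median log2 FPKM over the tested genes in each library (points), with group mean and SD (bars, n = 3), for raw FPKM, raw FPKM with 1 spike-in factor per library, and the deposited spike-in normalised FPKM. Raw medians lie between 3.66 and 3.69, normalised medians between 3.39 and 4.09, and each mutant group overlaps wild type in both spike-in scalings. With 1 factor every Ts1Rhr library lies below every HMGN1-overexpressing one.

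The genes of the triplicated region were higher in Ts1Rhr cells. Of its 29 listed genes, 16 were tested on chromosome 16, and 14 of these were above wild type. Their median log2 fold change was 0.59, which is 0.47 above that of other genes, a relative fold of 1.38 (p = 0.00105, two-sided permutation test with random lists). By RefSeq order these 16 are also all of the tested genes between Cbr1 and Fam3b. Over all genes tested, 3 rose, and 6 did adjusted over the list alone. Erg, an ETS transcription factor, rose 2.90-fold from 8.02 ± 1.14 to 23.2 ± 2.83 FPKM (limma, adjusted p = 0.011). Ttc3, a ubiquitin ligase gene, rose 2.14-fold (limma, adjusted p = 0.0351) and Chaf1b, a subunit of the chromatin assembly factor, 2.10-fold (limma, adjusted p = 0.0481). With HMGN1 overexpression the log2 fold changes of Erg, Chaf1b and Ttc3 against wild type were 0.92, 0.82 and 0.21 (standard errors 0.25, 0.23 and 0.22), none of them called. Higher levels of Erg and Chaf1b were thus not confined to Ts1Rhr, which lay 0.62, 0.26 and 0.88 above HMGN1 overexpression for these genes. The kinase gene Dyrk1a stood at 36.2 ± 2.44 against 18.2 ± 2.92 FPKM and the proteasome chaperone gene Psmg1 at 9.33 ± 1.95 against 5.36 ± 1.46, without passing (limma, adjusted p = 0.0565 and 0.147). On raw FPKM the region lay 0.36 above other genes (permutation p = 0.00876).

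The 30 tested genes of a list outside the segment on the same chromosome lay at -0.21 relative to other genes (permutation p = 0.132) and 0 of them rose (limma; 1 adjusted over the list alone). Runx1, a blood cell transcription factor in that list, was 37.5 ± 8.52 against 19.7 ± 2.32 FPKM (limma, adjusted p = 0.08). Against the HMGN1-overexpressing cells, which also differ in background by the labels, the region lay 0.60 above other genes, a fold of 1.51. All 16 were above the median gene (permutation p = 1e-05, the smallest these draws can give). HMGN1-overexpressing cells themselves showed -0.11 for the region relative to other genes against wild type (permutation p = 0.247). Their value for the list outside the segment, where no difference in copy number is expected, was -0.18 (permutation p = 0.0359; 0.0318 on raw FPKM). Without WT replicate 2 the Ts1Rhr value against wild type was 0.30 and no longer passed (permutation p = 0.0577). It stayed between 0.38 and 0.53 without any other single library.

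**Figure D2:**
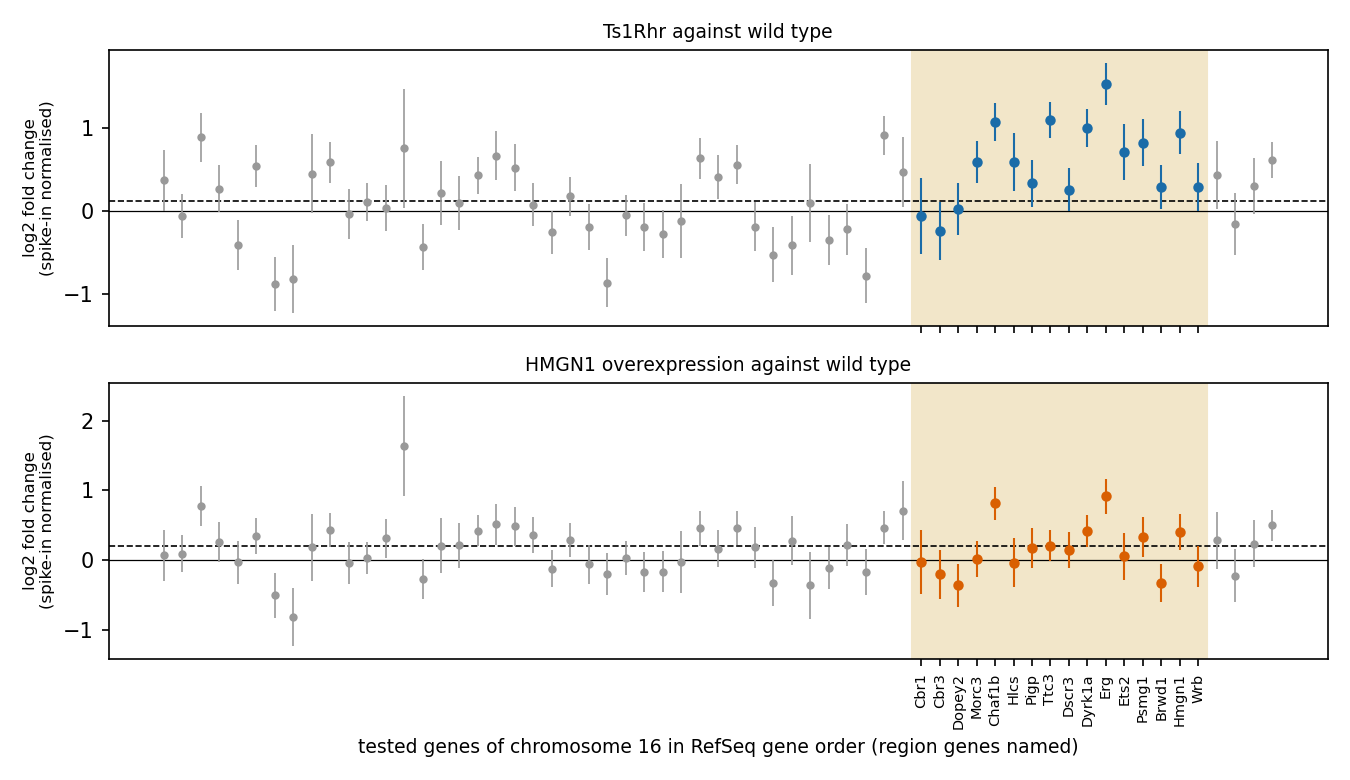
Log2 fold changes (points, with standard errors) of tested genes along chromosome 16 in RefSeq order, for Ts1Rhr (top) and HMGN1 overexpression (bottom) against wild type, on spike-in normalised FPKM. The shaded genes belong to the triplicated segment, the dashed line is the median of all tested genes, and the shaded genes have a median of 0.59 in Ts1Rhr and 0.10 with HMGN1 overexpression.

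Across the genome, 62 of the 10878 tested genes changed in Ts1Rhr against wild type (limma, Benjamini-Hochberg), 46 higher and 16 lower, with 2119 at an unadjusted p under 0.05. Among called genes with a mean of at least 5 FPKM and no overlap between groups, with small RNAs left out by the rule fixed beforehand, the largest increases were in Fgf13, an intracellular member of the fibroblast growth factor family, which rose 5.28-fold from 2.70 ± 0.700 to 14.1 ± 2.20 FPKM (limma, adjusted p = 0.000991), and Ccdc135, which rose 3.17-fold (limma, adjusted p = 0.00884). Kit, the stem cell factor receptor of early progenitors, rose 3.13-fold from 3.06 ± 0.753 to 9.37 ± 0.671 FPKM (limma, adjusted p = 0.0151). Gfra2, Tmem59l, Erg, Ska1 and Amotl1 completed the 8 largest, with folds from 2.86 to 3.00. The largest decreases by the same rule included genes of the extracellular matrix. Sfrp2, a secreted Wnt antagonist, fell from 24.5 ± 4.60 to 1.60 ± 1.74 FPKM, the matrix proteoglycan gene Bgn from 31.2 ± 8.26 to 3.85 ± 2.95, and Sparc from 12.9 ± 3.93 to 1.70 ± 1.19 (limma, adjusted p = 0.000991, 0.00884 and 0.00718). Igj, the immunoglobulin joining chain, fell from 23 ± 8.44 to 5.09 ± 2.59, and Akr1b8, Lox, Copz2 and Ccl7 fell too. The small nucleolar RNA rows left out had larger folds and varied widely, and are named after their values were seen. Snord17 stood at 19.3 ± 13.5 against 0.0914 ± 0.00846 FPKM and Snord15a at 0.109 ± 0.00679 against 123 ± 103 (limma, adjusted p = 0.00884 and 0.0208), and Snora74a was lower at a fold of 0.0129 (limma, adjusted p = 0.033).

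On raw FPKM 963 genes were called, 467 higher and 496 lower, and all 62 were among them. The split moved with the scaling. With every library shifted to the same median it was 251 higher and 442 lower, with 1 spike-in factor per library 16 and 28, and with raw FPKM rescaled to the same sum 710 and 234. With the myeloid score of each library as a covariate, chosen after seeing the data, 2 of the 62 stayed called, Fgf13 and Hmga2, and 1 of the 963. The median absolute log2 fold change of the 62 went from 1.51 to 1.39 and their median standard error from 0.28 to 0.32, with all 62 in the same direction, and for the 963 from 0.83 to 0.52 and from 0.20 to 0.23. The score did not overlap between Ts1Rhr and wild type, so it takes up part of the group difference. Normalised values of the groups did not overlap for 2363 genes higher and 917 lower in Ts1Rhr, 30.2% of genes where chance gives 10% for a single gene. On raw FPKM there were 2081 higher and 2011 lower, 37.6%. Raw library medians were nearly equal, so raw FPKM cannot show a shift of all genes. The even raw split therefore does not tell whether the excess of higher genes is real or came with the scaling. Genes of a library move together, so these shares can stray far from 10% without a group effect, and the excess was not tested. The count of 62 calls rested on single libraries, being 41, 5 and 12 without Ts1Rhr replicates 1, 2 and 3, and 17, 34 and 4 without WT replicates 1, 2 and 3. It was 203 and 125 without HMGN1_OE replicates 1 and 2, which only lend their spread. On raw FPKM it was 293, 3 and 1 without Ts1Rhr replicates 1, 2 and 3, and 1, 535 and 2 without WT replicates 1, 2 and 3. Fgf13, Hmga2 and Sfrp2 were the 3 genes called without any single library.

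Genes of the B cell progenitor and of the cell cycle were higher in Ts1Rhr than in wild type relative to other genes, and myeloid markers were lower. Of 28 pro-B identity genes 25 were higher, with a median of 0.38 above all genes (camera, adjusted p = 2.62e-05; adjusted p = 0.738 with an estimated correlation). Kit and Erg rose, and 10 did adjusted over the list alone. Erg also belongs to the triplicated region, so its rise is not separate from that of the region. Rag2, part of the recombinase that joins immunoglobulin segments, was 15.9 ± 3.71 against 7.22 ± 1.16 FPKM without passing (limma, adjusted p = 0.0565). Of 26 DNA replication genes 3 rose and 17 did adjusted over the list alone, with a median of 0.54 above all genes (camera, adjusted p = 1.14e-07; adjusted p = 0.738 with an estimated correlation). These were the cyclin gene Ccne2, up 2.86-fold, the clamp loader gene Rfc3, up 2.29-fold, and the DNA polymerase gene Pola1, up 2.12-fold (limma, adjusted p = 0.0209, 0.0481 and 0.0481). Of 25 mitosis genes 0 rose and 15 did adjusted over the list alone, with 24 higher (camera, adjusted p = 3.37e-07; adjusted p = 0.738 with an estimated correlation). The kinetochore genes Cenpe and Cenpf stood at 46.1 ± 6.85 against 23.4 ± 3.53 and 29.4 ± 4.26 against 15.0 ± 3.10 FPKM (limma, adjusted p = 0.0704 and 0.0708).

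All 21 tested myeloid markers were lower, with a median of -1.04 relative to all genes (camera, adjusted p = 6.75e-10; adjusted p = 0.738 with an estimated correlation). Over all genes tested 0 of them fell (limma), and 9 did adjusted over the list alone. The macrophage growth factor receptor gene Csf1r was 86.8 ± 25.9 against 209 ± 75.3 FPKM and the macrophage protein gene Cd68 106 ± 16.1 against 267 ± 141 (limma, adjusted p = 0.109 and 0.128). Of 4 stromal markers 3 fell, namely Sparc, Fn1 and Col1a2, with folds of 0.117, 0.146 and 0.153. Without WT replicate 1 the myeloid median relative to all genes was -0.81, with all 21 still lower.

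Of the other lists in Ts1Rhr, polycomb repressive complex 2 had 10 of 11 members higher (camera, adjusted p = 0.0198) and MYC and ribosome biogenesis 20 of 24 (camera, adjusted p = 0.0147), both with an adjusted p = 0.738 with an estimated correlation. In these lists 0 genes passed limma, and 4 and 0 did adjusted over the list alone. Immediate early and heat shock genes, with Fos at 37.9 ± 15.5 against 100 ± 48.2 FPKM, were lower (camera, adjusted p = 0.00166), as was the respiratory chain (camera, adjusted p = 0.0147), and none of their genes passed limma. Both had an adjusted p = 0.738 with an estimated correlation. With the myeloid covariate, chosen after seeing the data, the immediate early and heat shock median relative to all genes went from -0.58 to -0.19. On raw FPKM it went from -0.60 to 0.0041. Cytosolic ribosomal proteins lay at -0.21 relative to all genes (camera, adjusted p = 0.0198; adjusted p = 0.738 with an estimated correlation) and at 0.07 on raw FPKM (camera, adjusted p = 0.34), so that their direction turned with the scaling. The call of the respiratory chain was lost on raw FPKM (camera, adjusted p = 0.34), and without WT replicate 1 it and that of the ribosomal proteins were lost too (camera, adjusted p = 0.121 and 0.124). No call of any list in this comparison held with the estimated correlation. By fry, 0 lists moved on balance in 1 direction and 7 changed in either direction on normalised FPKM, against 7 and 20 on raw FPKM. Later B cell stages, dendritic cell markers, RNA polymerase II factors, glycolysis, cholesterol synthesis, the type I interferon response, interferon receptors, p53 targets, the unfolded protein response, histones, nucleosome-binding HMG proteins and strain-variable genes were not called by camera (adjusted p from 0.0589 to 0.828). Within these, Asns, asparagine synthetase, rose 2.20-fold (limma, adjusted p = 0.0481) and Hmga2, an HMG chromatin protein, fell to a fold of 0.171 (limma, adjusted p = 0.000991). Among 2 tested erythroid markers Car2, a carbonic anhydrase, rose 2.31-fold (limma, adjusted p = 0.041). Of the T and NK, polycomb-marked developmental and sex-linked lists 2, 2 and 3 genes were tested and 0 passed (limma), with 1, 0 and 0 adjusted over the list alone, and mast cell and mitochondrially encoded genes had 0 tested members.

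**Figure D3:**
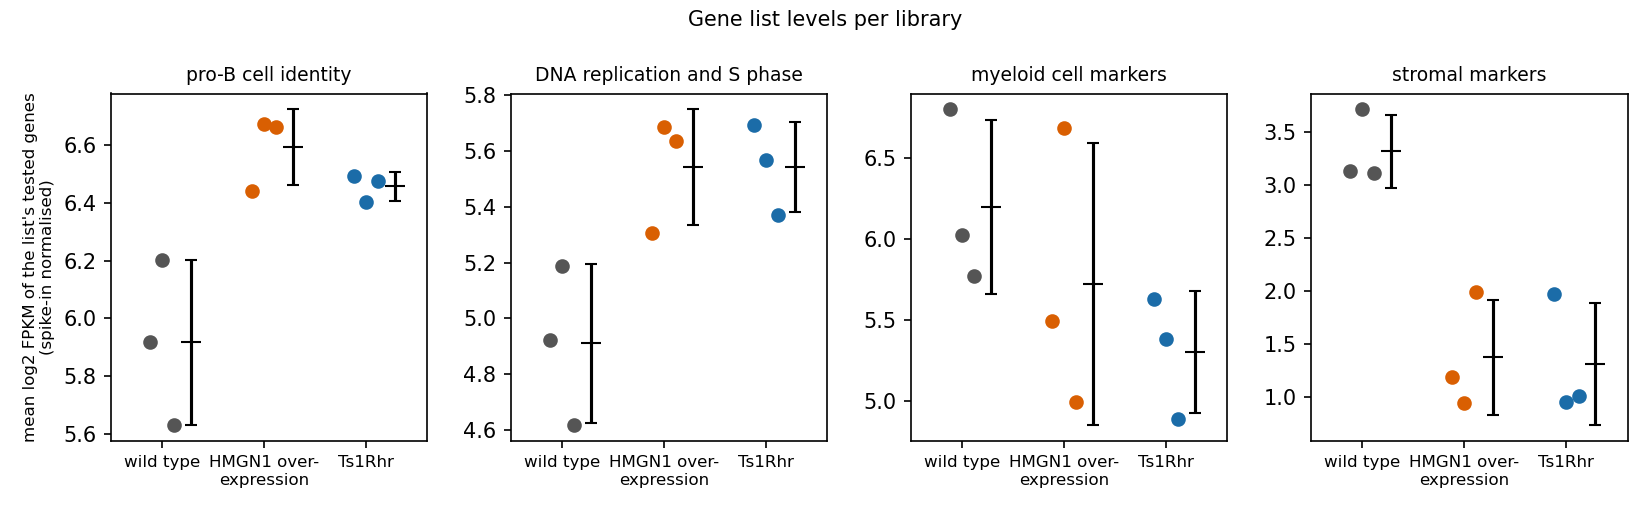
Mean log2 spike-in normalised FPKM of the tested genes of 4 gene lists in each library (points), with group mean and SD (bars, n = 3). For pro-B identity, S phase and stromal markers both mutant groups lie on 1 side of every wild-type library (exact permutation p = 0.1, the smallest possible), and for myeloid markers Ts1Rhr does (exact permutation p = 0.1) while HMGN1 overexpression overlaps wild type (exact permutation p = 0.4).

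With HMGN1 overexpression 10 genes were called against wild type, 1 higher and 9 lower (limma, Benjamini-Hochberg), with 1276 at an unadjusted p under 0.05. Mid1, a microtubule-associated ubiquitin ligase gene on the X chromosome, rose 9.45-fold from 2.39 ± 0.293 to 30.2 ± 20.9 FPKM (limma, adjusted p = 0.0247), with 6.39, 45.2 and 39.1 FPKM in replicates 1, 2 and 3. Sfrp2, Igj, Bgn, Sparc, Lox, Col1a2 and Hmga2 fell, Sfrp2 to 1.93 ± 0.708 and Igj to 2.32 ± 1.49 FPKM (limma, adjusted p = 0.0074 and 0.00646). The remaining calls were Timp1, an inhibitor of matrix proteases named after its values were seen, which fell from 7.32 ± 1.31 to 0.761 ± 0.695 FPKM (limma, adjusted p = 0.0074), and Rpl26, which is listed at 0.01 raw FPKM in all 3 HMGN1_OE libraries (limma, adjusted p = 0.0278 on normalised and 0.135 on raw FPKM). Values short of the threshold were higher for Dntt, the enzyme that adds bases at immunoglobulin joints, at 144 ± 11.4 against 51.9 ± 10.5 FPKM (limma, adjusted p = 0.0601), and for Kit and Fgf13 at folds of 2.64 and 2.67 (limma, adjusted p = 0.0657 for each). On raw FPKM 4 genes were called, all lower, namely Hmga2, Igj, Lox and Sparc. The count of 10 was 1 without WT replicate 2 and 1 without WT replicate 3, and 17 and 16 without HMGN1_OE replicates 2 and 3. With 1 spike-in factor per library it was 20, split into 7 higher and 13 lower. With the myeloid covariate 4 of the 10 stayed called, and the median absolute log2 fold change of the 10 went from 3.19 to 3.37. The raw count of 4 was 12 and 7 without HMGN1_OE replicates 2 and 3, 7 without Ts1Rhr replicate 1, and 2, 0 and 1 without WT replicates 1, 2 and 3. Mid1 had adjusted p values up to 0.286 (limma) when single libraries were left out, and 0.101 on raw FPKM.

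With HMGN1 overexpression, pro-B and cell cycle genes were higher than in wild type relative to other genes and myeloid markers lower, against the same wild-type libraries as for Ts1Rhr. Of 28 pro-B genes 27 were higher, with a median of 0.39 above all genes (camera, adjusted p = 6.93e-10; adjusted p = 0.808 with an estimated correlation), and 0 rose over all genes tested (limma) against 9 adjusted over the list alone. All 26 DNA replication and all 25 mitosis genes were higher, with medians of 0.46 and 0.44 above all genes (camera, adjusted p = 6.93e-10 and 9.46e-10; adjusted p = 0.808 with an estimated correlation for both), and 0 of either rose (limma), against 16 and 8 adjusted over the list alone. Cdc6, which licenses replication origins, was 21.9 ± 5.15 against 10.9 ± 1.84 FPKM and the mitotic kinase gene Aurka 21.1 ± 3.48 against 12 ± 1.33 (limma, adjusted p = 0.184 and 0.278). All 21 myeloid markers were lower, with a median of -0.64 relative to all genes (camera, adjusted p = 6.93e-10; adjusted p = 0.808 with an estimated correlation). Without WT replicate 1 that median was -0.41, with 15 of 21 lower. MYC and ribosome biogenesis, polycomb repressive complex 2 and RNA polymerase II factors were higher (camera, adjusted p = 0.00131, 0.0148 and 0.0349; adjusted p = 0.947, 0.947 and 0.979 with an estimated correlation). Immediate early and heat shock genes were lower (camera, adjusted p = 0.00129; adjusted p = 0.947 with an estimated correlation). Of the 4 stromal markers 2 fell, Sparc and Col1a2. The other tested lists were not called (camera, adjusted p from 0.145 to 0.992), and fry called 0 lists on balance and 2 for change in either direction, against 0 and 4 on raw FPKM.

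The direct comparison of the mutant groups called 0 genes (limma, Benjamini-Hochberg) on normalised and 0 on raw FPKM, with 475 and 963 at an unadjusted p under 0.05. By the labels these groups differ in background as well as genotype, so the differences below may come from either. Mid1 stood at 2.80 ± 1.22 FPKM in Ts1Rhr against 30.2 ± 20.9 (limma, adjusted p = 0.152). Nme3, Cxx1a and Ifitm1 lay at folds of 0.389, 0.411 and 0.315 (limma, adjusted p = 0.45, 0.45 and 0.549) and Ttc3 at 1.85 (limma, adjusted p = 0.976). Besides the triplicated region, camera called ribosomal proteins (adjusted p = 9.08e-05), the respiratory chain (adjusted p = 0.00829), myeloid markers (adjusted p = 0.0132) and histones (adjusted p = 0.0282) lower in Ts1Rhr, and these had an adjusted p = 0.998 with an estimated correlation, against 0.522 for the region. On raw FPKM the calls of ribosomal proteins, the respiratory chain and histones were lost (camera, adjusted p = 0.316, 0.316 and 0.0531), ribosomal proteins lying at -0.08 relative to all genes against -0.31 on normalised FPKM. The myeloid call stayed (camera, adjusted p = 0.0169), and S phase and mitosis were called higher (camera, adjusted p = 0.00665 and 0.0142), all 3 with an adjusted p = 0.859 with an estimated correlation. On raw FPKM the region alone held with an estimated correlation (camera, adjusted p = 0.00662). The myeloid call was lost without Ts1Rhr replicate 3 (camera, adjusted p = 0.318), and the count of 0 genes became 2, 3 and 3 without HMGN1_OE replicates 1, 2 and 3 and 1 without Ts1Rhr replicate 2 or 3.

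Fold changes of both mutant groups against wild type correlated across genes, with Pearson's r = 0.69 and Spearman's rho = 0.74 over the 10878 genes, which are not independent replicates, and 78.7% had the same sign. Unchanged groups simulated against the same controls gave a median r of 0.51 (-0.25 to 0.85), and in 13 of 100 draws r was as large as observed. The covariance was 0.220 against a simulated median of 0.101, a difference of 0.119, and the upper end of the simulated range was 0.173. Of the lower calls, 16 in Ts1Rhr and 9 with HMGN1 overexpression, 7 were shared, where independent lists give 0.0132, namely Bgn, Col1a2, Hmga2, Igj, Lox, Sfrp2 and Sparc. The 3 controls could not be split into groups of at least 2, so part of the excess of this overlap over independent lists may come from the shared wild-type libraries.

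**Figure D4:**
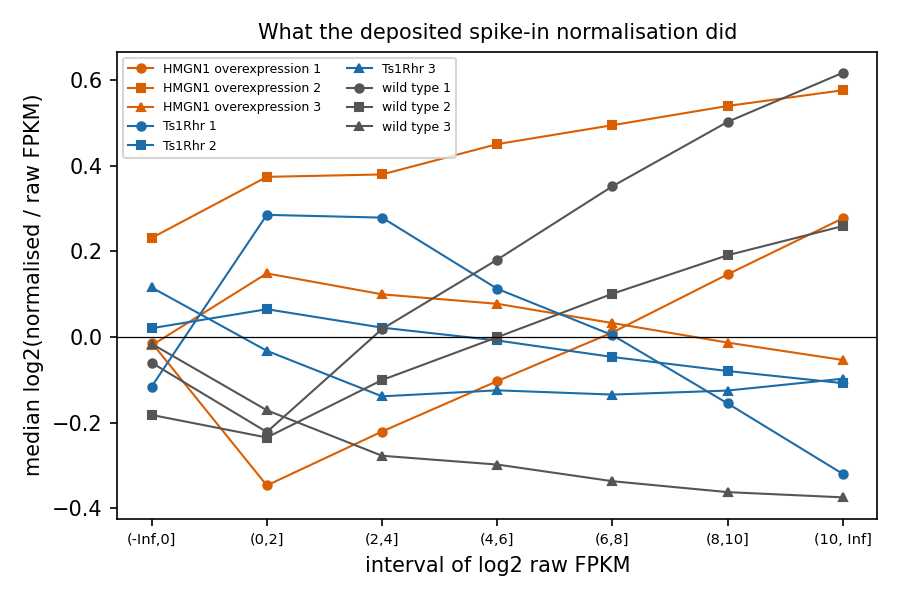
Median log2 ratio of spike-in normalised to raw FPKM, by interval of log2 raw FPKM, for each library (lines). The correction rises with expression in some libraries and falls in others, so that it changes folds by expression level; in Ts1Rhr against wild type the median log2 fold change is 0.25 in the lowest and -0.03 in the highest of 3 equal groups of genes by mean FPKM.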

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

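No test was run on the genes here, which were picked out after their values were seen because they lay outside the tested genes and above the wild-type level in a mutant library. Gm5512, a row below the expression filter of the tests, read 5.05 FPKM in HMGN1_OE replicate 3 and 1.5 in HMGN1_OE replicate 1, and was listed at 0.01 in the other libraries, among them all wild-type ones. The Y-linked genes Kdm5d and Uty, also below that filter, read 6.23 and 5.21 FPKM in Ts1Rhr replicate 3 and at most 0.0972 FPKM elsewhere. These values stand beside the Ddx3y, Eif2s3y and Xist levels of that library, and the other 8 libraries had Xist between 94.2 and 193 FPKM.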

How the results depend on the processing

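The myeloid covariate, the omission of small RNA and 0.01-listed genes, 0.1 added on top, the gene lists without a library, the global level between mutants and the region by gene order were chosen after seeing the data. Calls for Ts1Rhr against wild type on normalised FPKM (62) became 8 without a filter, 267 with only the compared groups, 693 with equal library medians, 110 without small RNA and 0.01-listed genes and 2 with a myeloid covariate. On raw FPKM (963) they became 264 without a filter and 1 with the covariate. Calls for HMGN1 overexpression on normalised FPKM (10) became 19 with a pseudocount of 1, 4 without a filter, 18 with only the compared groups, 20 with 1 spike-in factor, 20 without small RNA and 0.01-listed genes and 4 with the covariate. On raw FPKM (4) they became 19, 27 and 9 under the first of these, and 8 without those genes. Between mutants (0) there were 4 with 1 spike-in factor and 2 without those genes. Array weights gave 2069, 1663 and 11 normalised calls and 11 raw HMGN1 calls. On normalised values their fit stopped before convergence and gave WT replicate 2 a weight of 9.44, with HMGN1_OE replicate 3 next at 2.73. The counts may lean on such libraries, which was not tested. A pseudocount of 0.01 could not be run on normalised values, which already hold about 0.1.

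Replicate numbers did not pair the libraries, for same-numbered deviations correlated between -0.13 and 0.16, over 0.1 in 2 of 9 pairs. With the replicate block the counts were 119, 314 (raw), 15, 4 (raw) and 5. All 40 called gene results named here other than the small nucleolar RNA rows, which were not followed, stayed called. Among the gene results followed, 12 that did not pass on normalised values passed on raw FPKM, and 6 that were called lost their call there. Whether such a gene passed thus depended on the values used.

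Leaving out 1 library at a time gave 4 to 203 and 1 to 1276 (raw) calls for Ts1Rhr, 1 to 17 and 0 to 12 (raw) for HMGN1 overexpression and 0 to 3 between mutants. The region value ranged from 0.30 to 0.53, the correlation of folds from 0.56 to 0.75, and the global differences from 0.04 to 0.22 and from 0.06 to 0.35. The Ts1Rhr global difference reversed to -0.36 for summed FPKM and -0.0729 with 1 spike-in factor, that of HMGN1 to -0.00759 for summed FPKM, and ribosomal proteins in Ts1Rhr to 0.0716 on raw FPKM. List calls went from 10 and 8 to 0 and 0 with a correlation estimated from the data in place of the preset 0.01, so these calls rest on the preset value. All 62 and 10 calls kept their direction without any single library, but 40 of the 62 were called in fewer than 5 of 9 such fits. Where not stated, the cause was not tested. Depth is unknown and limits low genes to an unknown degree.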

Other observations

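The tests here of the myeloid share, of the spike-in scaling of the S phase list, of the myeloid covariate, of the genes beside the segment and of the pro-B share were chosen after the result was seen. Scd1, Scd2 and Elovl6 were called for Ts1Rhr against wild type and are named after their values were seen, with no test of a group they belong to. Scd1 and Scd2, the stearoyl-CoA desaturases that make monounsaturated fatty acids, rose 2.48-fold from 18.9 ± 3.70 to 46.7 ± 5.67 FPKM and 2.31-fold from 27.2 ± 5.77 to 62.2 ± 8.44 (n = 3; limma, adjusted p = 0.0174 and 0.0389). Elovl6, which lengthens fatty acids, rose 2.48-fold from 19.6 ± 3.67 to 49.2 ± 11.9 FPKM (limma, adjusted p = 0.0351). With HMGN1 overexpression the folds were 1.59, 1.72 and 2.02 (limma, adjusted p = 0.312, 0.289 and 0.227), and the difference between the mutants did not pass for any of them (limma, adjusted p = 0.988). The collagen gene Col6a1, also chosen after its values were seen, fell in Ts1Rhr from 5.33 ± 0.648 to 0.489 ± 0.232 FPKM (limma, adjusted p = 0.00718).

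Pro-B and cell cycle genes were higher and myeloid genes lower in Ts1Rhr. The authors' spike-in scaling is argued against as the cause, for the S phase median was 0.6655 on raw FPKM. A smaller share of myeloid RNA stays open, since the raw myeloid median of -0.8719 is part of the pattern itself and decides nothing, and with the myeloid score as a covariate, which does not overlap between the groups, the raw S phase median relative to all genes went from 0.65 to 0.40 and the pro-B median from 0.58 to 0.22. Cell cycle scores were higher by about as much as pro-B scores, with a difference of 0.03142 (standard error 0.0966, exact permutation p = 0.9), as a larger pro-B share may give. An effect of the genotype on the cultures' makeup, strain and a change within pro-B cells stay open and untested, and the protocol names no sort that would remove myeloid cells.

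Fold changes in Ts1Rhr against wild type differed by expression level, the median being 0.275 higher in the lowest than in the highest of 3 equal groups of genes. On raw FPKM the gap was -0.0333, so it came in with the authors' level-dependent correction. With 1 spike-in factor per library the gap was -0.0328, a share of -0.1192 of the original. Such a factor moves all genes of a library nearly alike, so it could only return about the raw gap. No biological explanation of this gap was tested.

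Triplicated genes were higher in Ts1Rhr relative to other genes. A regional difference that raised genes on both sides of the segment would raise the flanking list too, and it lay at -0.2095 relative to other genes (standard error 0.111). A strain difference need not move genes in 1 direction, so this median cannot decide on strain. The 20 tested genes before the segment had a median log2 fold change of -0.20. The nearest of them, Setd4 and Runx1, lay at 0.47 and 0.91 (standard errors 0.42 and 0.24), and the next, Rcan1, at -0.79. The 4 after the segment lay at 0.2455 relative to other genes (standard error 0.206), too few to exclude a difference that reaches beyond that end. A larger pro-B share would shrink the value against HMGN1-overexpressing cells, whose pro-B list lay 0.02 from that of Ts1Rhr, and it was 0.5966 there (standard error 0.0841). By mean log2 level the pro-B list stood at 6.46 in Ts1Rhr and 6.59 with HMGN1 overexpression, and at 6.50 and 6.42 on raw FPKM. The myeloid list stood at 5.30 ± 0.38 and 5.72 ± 0.87. The mutant groups may thus differ in makeup, which this comparison cannot set aside. The extra gene copy may account for the higher level of the triplicated genes, as a hypothesis, and a strain difference inside or outside the segment stays open.

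Of 4 tested stromal markers 3 were lower in each mutant group than in wild type, with 3 passing in Ts1Rhr and 2 with HMGN1 overexpression (limma), and no set test was made for so short a list. Stromal cells in the wild-type cultures may be the source. Of 5 fibroblast genes beyond those tested, among them Col3a1 of the same stromal list, 4 had a wild-type mean of at least 1 raw FPKM. Of these 3 were lower in both mutants, short of the bound of 4 set beforehand, so the test left this open. The exception was Thy1, at 13.0 ± 8.03 raw FPKM with HMGN1 overexpression against 7.85 ± 1.14 in wild type, so the outcome turned on that gene. The raw count of 3 also rested on Postn, near the bound of 1 FPKM. It stood at 1.07 ± 0.127 raw FPKM in wild type, 0.823 ± 0.693 with HMGN1 overexpression and 0.913 ± 0.418 in Ts1Rhr. Normalised, it was higher in both mutants, at 0.927 in wild type against 1.09 and 1.07. On normalised FPKM 3 genes reached that mean and 2 were lower in both.

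With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The grouping by genotype gave the most calls, as 1 of the 10 splits, in 4 comparisons: 62 against at most 2 in the others for Ts1Rhr, 10 against 2 for HMGN1 overexpression, and on raw FPKM 963 against 1 and 4 against 0. For the triplicated genes it gave 0.4677 against 0.219. Between the mutants 10 of 10 splits gave at least its 0 calls, the highest 2.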
